A study of Pleurotus ostreatus with 4 samples.

How the data were processed

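Transcript abundance was measured by RNA sequencing in the oyster mushroom Pleurotus ostreatus, a white-rot basidiomycete, strain P739. The samples were mycelium, primordium, young fruit body and mature fruit body, with 1 library for each of the 4 stages. Per the labels' protocols, material was frozen on dry ice, RNA was extracted with Trizol reagent, and libraries were sequenced on an Illumina HiSeq instrument. Each column of the table was assigned to its stage by the short name in the sample's description. No stage had a replicate library, so no p-value, standard error or test between stages is given.

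The deposited values are FPKM, fragment numbers scaled by sequence length and by library total, per the file headers. The authors listed 51131 sequences with 4 decimals for each value. The aligner, the counting tool, the set of sequences the reads were aligned to and any filter are not given in the sources used here. Identifiers had the form of numbered contigs within clusters (39842 contigs in 6528 clusters, with a median of 3 and up to 156 contigs in a cluster) or of single unigenes (11289). How fragments were divided between contigs of 1 cluster is not given in the sources used here either. The table paired no identifier with a gene name, a position or a description. Of the 51131 identifiers, 0 matched a RefSeq table of 11849 genes of strain PC9. The 35 gene lists drawn up in advance, on cell wall, lignocellulose, hydrophobin, meiosis and other functions, were patterns on gene descriptions, so they had no members here and give no result. Genome positions are not given for the same reason.

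Although the table used here holds FPKM only, the low values lay on steps of whole fragments, which allowed the fragment counts to be recovered. Ratios of the library totals used as FPKM denominators were taken from the most common FPKM ratio of each fruiting library to mycelium. Sequences at this ratio, within a tolerance set from the rounding of FPKM, were taken to have equal counts (1179 to 1285 sequences for each such pair). The absolute denominator was the period that divided the product of denominator and length into whole lengths over 8199 sequences. Each product was taken from the smallest whole counts in the ratio of the 4 libraries. A factor common to the counts therefore also divided the length found in this search. The phases agreed at this period with a coherence of 0.893, against 0.016 at double the period and a median of 0.0089 over the other periods searched. For each sequence, the smallest length of at least 200 nt that gave whole counts in all 4 libraries was then taken. This shortest length was set because, among the lengths found in the period search, 39 were in the 20 nt below 200 and 322 in the 20 nt from 200 upward. All 50567 sequences above 0 gave whole counts within a tolerance set slightly above the rounding error of 5e-05 FPKM. The largest difference between deposited and back-computed FPKM was 5.1e-05. Lengths outside the tolerance were not accepted, so this difference is not a separate check. Among the 17726 sequences above 0.5 FPKM in all libraries, the share with whole counts was 100.0%, against 0.395% when the denominators were shifted by up to 0.21%. Shifted denominators were not tried on the other sequences, so whole counts there are not a check of the denominators. Counts that shared a common factor are understated by that factor, because the smallest solution was taken. The recovered fragments summed to between 98.6% and 98.8% of the denominators.

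The recovery and the calls were tested on simulated data made from the primordium to young fruit body step, with 50567 sequences and 200 of them changed. The denominators were recovered, and 95.4% of the sequences had their 4 counts recovered exactly. A further 4.38% had the true counts divided by 1 common whole factor, which leaves ratios between libraries as they were. The changed sequences were drawn from those of at least 20 FPKM and were changed 3-fold or 4-fold. All of them were called in the right direction (100% each), and 3 of 50367 unchanged sequences were called. Most of the unchanged sequences could not be called, because a call needs at least 5 FPKM in the higher library. In the real step, 6820 sequences met this minimum. Calls of 2-fold changes, and of changed sequences between 5 and 20 FPKM, were not tested.

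Sequences with at least 1 FPKM in at least 1 library were compared (22307 sequences). A sequence was called higher or lower where log2(FPKM + 1), with its pseudocount of 1, differed by at least 1 and the FPKM was at least 5 in the higher of the libraries compared. Such a difference understates the change of sequences of low abundance, and folds of named sequences are therefore given as ratios of FPKM. The stages were compared in the order of development, as 3 consecutive steps, and each fruiting stage was compared with mycelium. The rule for named sequences, for the case in which no descriptions can be had, was the 2 largest differences in each direction and step among called sequences with at least 10 FPKM in the higher library. These rules and most alternatives were fixed before the data were examined. The alternatives were other pseudocounts, other minimum FPKM values, a 4-fold threshold, 4 other scalings of the libraries and, added later, 2 scalings that keep the mean total, a correction for length, a criterion on the counting interval, and sums over clusters.

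Intervals on folds are exact 95% Clopper-Pearson intervals of the recovered counts, and the interval on a share of fragments is a 95% Wilson interval. For every share of fragments given, this interval is at most 0.0254 percentage points to either side. They cover counting error only, because fragments copied by PCR are not independent molecules and the spread between cultures was not measured. Shares of fragments are shares of the recovered fragments, which summed to between 98.6% and 98.8% of the denominators. The intervals do not cover this shortfall. A count of 0 allows up to 3 fragments, and a fold against it is a lower bound at that floor. Simulated unchanged libraries were drawn 20 times from the pooled rate of each sequence, with counting error only. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.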

Results

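The developmental stages of Pleurotus ostreatus strain P739 that were profiled were the vegetative mycelium, the primordium (the first compact tissue from which a mushroom grows), the young fruit body and the mature fruit body. Each stage was represented by 1 library, so differences between stages could not be set against the spread between replicates. Sequencing depth was nearly even. The denominators recovered from the FPKM steps were 15541785 fragments for mycelium, 15048631 for primordium, 15400578 for young fruit body and 15691317 for mature fruit body, the largest 4.27% above the smallest. One fragment on a sequence of 1000 nt was worth between 0.0637 and 0.0665 FPKM in these libraries. Of the 51131 sequences in the table, 18057 reached 1 FPKM in mycelium, 16214 in primordium, 16786 in young fruit body and 17076 in mature fruit body. In all, 564 sequences were at 0 in every library. The identifiers carry no gene names, so sequences are given by identifier and recovered length, and the function of none is stated. Counts and shares of sequences by fold, and median folds of groups, rest on log2(FPKM + 1), which understates differences at low FPKM. Folds of single sequences are ratios of FPKM. How fragments were divided between contigs of 1 cluster is not given in the sources used here, and its effect on the values of single contigs was not tested.

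The mycelium library was dominated by few sequences to a greater degree than the libraries of the fruiting stages. A single sequence of 524 nt, Unigene4844, reached 58060 FPKM in mycelium, which was 9.75% of the summed FPKM and 3.08% of the recovered fragments (95% Wilson interval 3.07% to 3.09%). It stood at 47.6 FPKM in primordium, 83.5 in young fruit body and 78.8 in mature fruit body. The highest FPKM in each of the 3 fruiting libraries belonged to Unigene4855 (426 nt), singled out after its values were seen, with 10896 in primordium, 12156 in young fruit body and 9060 in mature fruit body against 1269 in mycelium. The 10 sequences of highest FPKM made up 17.2% of the summed FPKM in mycelium, 8.30% in primordium, 8.13% in young fruit body and 8.16% in mature fruit body.

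Across the 22307 compared sequences, the fruiting libraries resembled one another more than any of them resembled mycelium. Pearson's r of log2(FPKM + 1) was 0.82 between mycelium and primordium, 0.81 between mycelium and young fruit body and 0.80 between mycelium and mature fruit body. Between primordium and young fruit body it was 0.98, between young and mature fruit body 0.97, and between primordium and mature fruit body 0.95. Spearman's rho gave the same order, from 0.64 for mycelium and mature fruit body to 0.92 for primordium and young fruit body. These correlations run across sequences, which are not independent replicates.

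The first comparison set primordium against mycelium. Of 8134 sequences with at least 5 FPKM in either library, 1311 were at least 2-fold higher in primordium and 2005 were at least 2-fold lower, 40.8% of the total. The sequences higher in primordium took 8.81% of the fragments in mycelium and 32.9% in primordium, whereas those lower in primordium took 30.4% in mycelium and 6.14% in primordium. The median fold, with FPKM as deposited, was 3.85 in the lower group and 2.81 in the higher group. These medians rest on log2(FPKM + 1), which understates differences at low FPKM. The median abundance was 16.9 FPKM in mycelium for the lower group and 36.7 FPKM in primordium for the higher group. At least 4-fold differences were found for 395 higher and 957 lower sequences, at least 16-fold differences for 111 and 171, and a log2 difference of at least 8 for 5 and 15.

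The largest difference toward primordium was that of CL3207.Contig2 (595 nt), at 3.46 FPKM in mycelium and 4598 FPKM in primordium. The ratio was 1329-fold, with a 95% counting interval of 941 to 1943 from 32 and 41173 fragments. CL5829.Contig1 (988 nt) stood at 5.28 FPKM in mycelium and 4573 in primordium, 867-fold higher (697 to 1092). Both remained abundant later, at 3858 and 3983 FPKM in young fruit body and 4263 and 3707 FPKM in mature fruit body. The largest difference toward mycelium was that of Unigene427 (702 nt), with 3102 FPKM in mycelium and 0.473 FPKM in primordium. It was 6553-fold lower, with an interval of 2808 to 20183 that reflects the 5 fragments found in primordium. The dominant mycelial sequence Unigene4844 was 1221-fold lower in primordium (1103 to 1355).

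Called sequences were found both among contigs of clusters (745 higher and 1211 lower) and among single unigenes (566 higher and 794 lower). The called share was 42.0% of the 4661 contigs and 39.2% of the 3473 unigenes with sufficient FPKM. By length, the called share was 42.6%, 46.7% and 43.1% in the 3 shorter groups and 32.6% in the longest, from 2395 nt upward. The 4 length groups were of about equal size over all compared sequences, but held 987, 2127, 2520 and 2500 sequences with sufficient FPKM, over which these shares are taken. Simulated unchanged libraries with counting error only gave at most 10 calls in 20 draws. The direction of the balance depended on scaling: 39.5% of the calls were higher in primordium with FPKM as deposited, but 54.9% (1886 higher and 1547 lower) after scaling to the upper quartile, which shifted the median log2 difference of all sequences by 0.19. Under every other alternative lower calls outnumbered higher ones, with 29.2% to 48.9% of the calls higher.

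**Figure D1:**
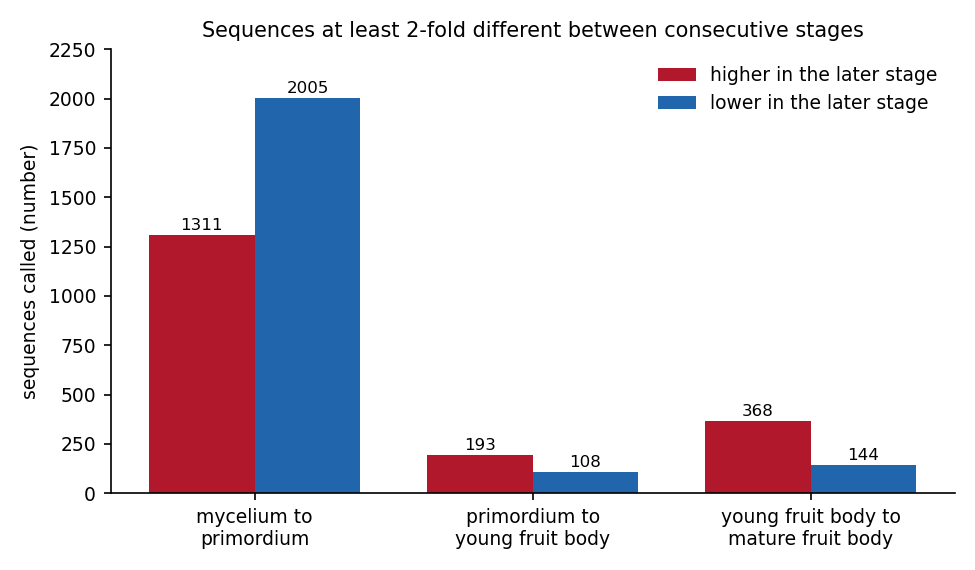
Number of sequences called at least 2-fold higher (red) or lower (blue) in the later stage of each step, on the vertical axis, for the 3 consecutive steps on the horizontal axis. The step from mycelium to primordium has 1311 and 2005 sequences, the next step 193 and 108, and the last 368 and 144, from 1 library per stage. In the first step the balance turned to 1886 and 1547 under upper-quartile scaling, the only alternative tried that reversed it.

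**Figure D2:**
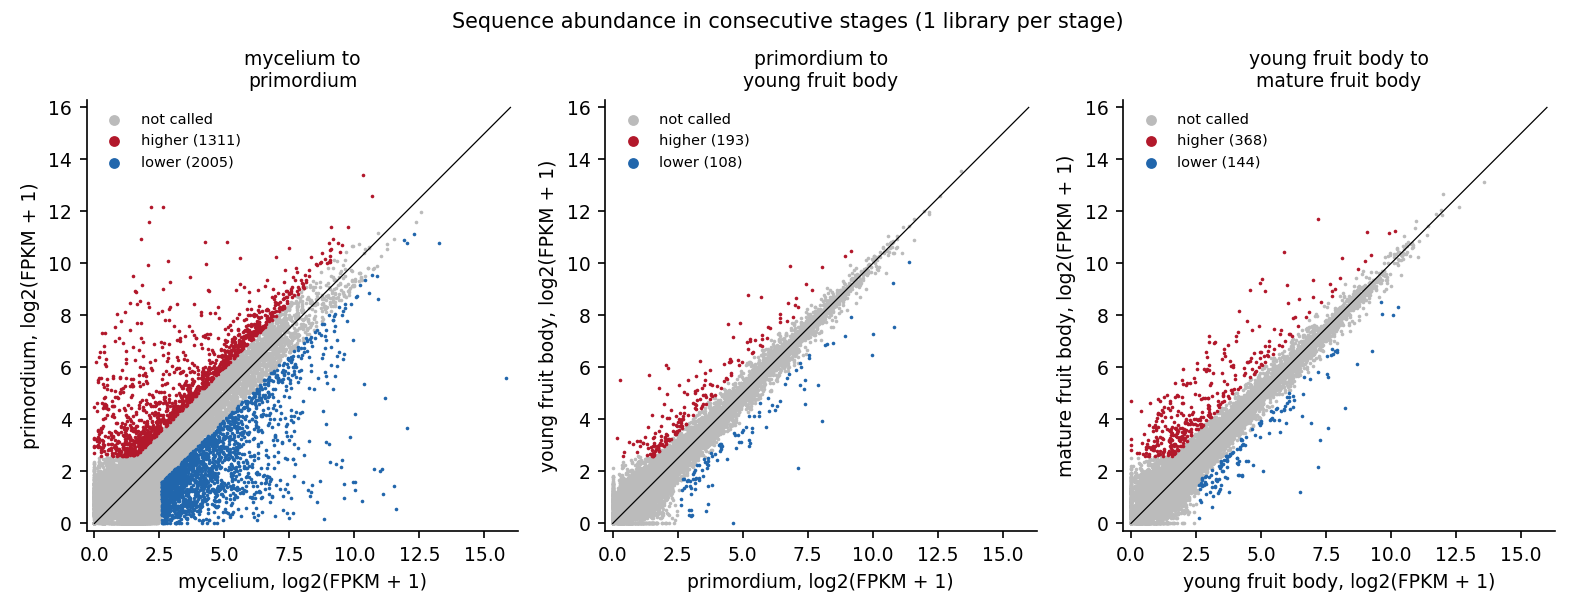
Abundance of each of the 22307 compared sequences in the earlier stage (horizontal axis) and the later stage (vertical axis) of each step, as log2(FPKM + 1). Red points were called higher, blue points lower and grey points were not called, and the line marks equal abundance; the cloud is widest in the step from mycelium to primordium, where Pearson's r is 0.82 against 0.98 and 0.97 in the later steps.

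Between primordium and young fruit body few sequences differed. Of 6820 sequences with sufficient FPKM, 193 were higher and 108 were lower in the young fruit body, 4.41% of the total, and 88.4% lay within 1.5-fold of equality. The higher sequences took 0.744% of the fragments in primordium and 2.39% in young fruit body, and the lower sequences 2.55% and 0.639%. Differences of at least 4-fold were found for 33 higher and 22 lower sequences, and of at least 16-fold for 3 and 3.

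CL6317.Contig1 (289 nt) had 0.230 FPKM in primordium, resting on 1 fragment, and 44.5 FPKM in young fruit body, resting on 198 fragments. Its ratio was 194-fold with a counting interval of 34.3 to 7680, and it had 0 fragments in mycelium, which allows up to 3, and 34.4 FPKM in mature fruit body. CL2597.Contig2 (952 nt) was 31.8-fold higher in young fruit body (21.0 to 50.4), at 51.0 against 1.61 FPKM. In the other direction, Unigene2861 (1029 nt) stood at 138 FPKM in primordium and 3.34 in young fruit body, 41.2-fold lower (31.4 to 55.2), with 15.2 FPKM in mature fruit body and 8.82 in mycelium. Unigene10085 (310 nt) had 24.01 FPKM from 112 fragments in primordium and 0 fragments in young fruit body, at least 38.2-fold lower at the floor of 3 fragments. Counting error alone gave at most 9 calls in 20 simulated draws of this step. The called share was 4.12% among unigenes and 4.65% among contigs.

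From young to mature fruit body, 368 sequences were higher and 144 were lower among 7055 with sufficient FPKM, 7.26% of the total. The higher group took 1.60% of the fragments in young fruit body and 6.11% in mature fruit body, and the lower group 2.06% and 0.601%. At least 4-fold differences were found for 139 higher and 26 lower sequences, and at least 16-fold differences for 8 and 3. The share of higher sequences among the calls was 71.9% at 2-fold and 84.2% at 4-fold, and the 16-fold numbers are too small to compare.

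CL3980.Contig3 (3668 nt) had a higher value at each stage than at the one before, with 2.07 FPKM in mycelium, 12.3 in primordium, 58.7 in young fruit body and 1404 in mature fruit body. Its last step was 23.9-fold (23.1 to 24.8). CL3924.Contig5 (658 nt) had 24.9 FPKM from 257 fragments in mature fruit body and 0 fragments in young fruit body, at least 84.1-fold higher at the floor of 3 fragments, and it had 4.60 FPKM in mycelium. Unigene7995 (1719 nt) was 66.7-fold lower in mature fruit body (48.0 to 95.5), at 1.33 against 89.0 FPKM, and CL6379.Contig1 (2066 nt) was 41.5-fold lower (34.5 to 50.4), at 3.55 against 147 FPKM. Both were more abundant in primordium, at 188 and 489 FPKM, than in any other library. Simulated unchanged libraries gave at most 8 calls in this step. By kind, 8.19% of contigs and 6.08% of unigenes with sufficient FPKM were called.

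**Figure D3:**
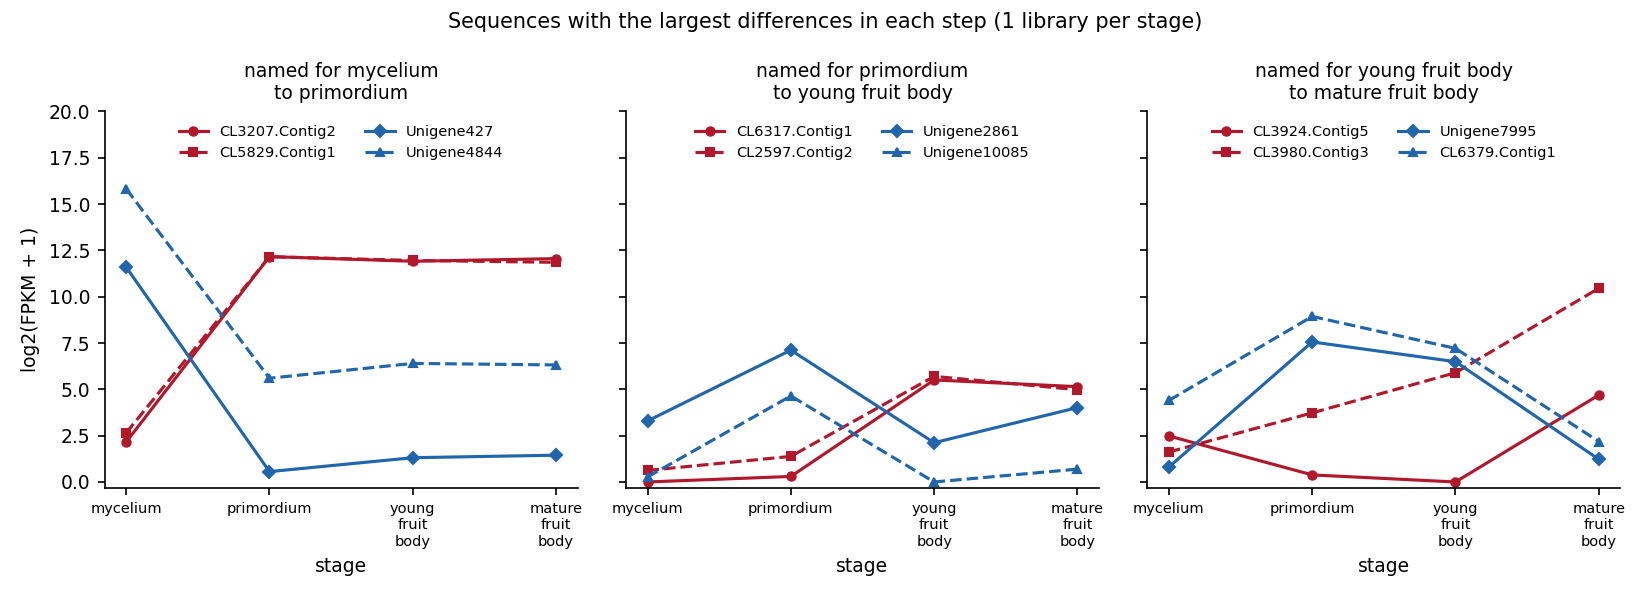
Abundance as log2(FPKM + 1), on the vertical axis, of the 2 sequences highest (red) and the 2 lowest (blue) in the later stage of each step relative to the earlier one, over the 4 stages on the horizontal axis; each point is 1 library. Of those named for the first step, CL3207.Contig2 has 4598, 3858 and 4263 FPKM and Unigene427 has 0.473, 1.48 and 1.72 FPKM in the fruiting stages, and Unigene7995 and CL6379.Contig1 have their highest value in primordium.

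The last comparison asked which sequences separated mycelium from all 3 fruiting stages. Against mycelium, 884 sequences were higher and 1657 were lower in primordium, young fruit body and mature fruit body alike. Under upper-quartile scaling the numbers were 1200 and 1302, so the size of the excess of lower sequences depended on scaling. With FPKM as deposited, these were 67.4% of the sequences higher in primordium and 82.6% of those lower in primordium. The sequences higher in all 3 fruiting stages took 5.47% of the fragments in mycelium, 24.1% in primordium, 25.7% in young fruit body and 25.9% in mature fruit body. Those lower in all 3 took 28.3% in mycelium, 5.33% in primordium, 4.64% in young fruit body and 4.53% in mature fruit body. Differences of at least 16-fold in every fruiting stage were found for 81 higher and 131 lower sequences. CL3207.Contig2 and CL5829.Contig1 were in the higher group, and Unigene427 and Unigene4844 in the lower group.

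Compared with mycelium one stage at a time, 1454 sequences were higher and 2045 lower in young fruit body, and 1519 higher and 2032 lower in mature fruit body. Only 24 sequences were called in opposite directions in different fruiting stages. Among the 7833 sequences that could be called in all 3 comparisons, independent lists would share 27.4 higher and 136 lower sequences, and simulated unchanged libraries shared at most 1 and 0. The simulation holds counting error only. The 3 comparisons used the same mycelium library, so their lists are not independent. This library cannot be split, so part or all of the overlap may come from the shared library.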

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

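Of the 14 alternatives 5 were chosen after the data had been seen: the length correction, the counting interval, the sums over clusters and both scalings that keep the mean total. With those 5, with a pseudocount of 0.1, and with median-of-ratios or upper-quartile scaling, all 8 counts stayed within 1.5 times the reported values. The step from mycelium to primordium held more calls than either later step under all 14. The other 6 alternatives moved counts, given here as higher and lower; thresholds, minimums and pseudocounts move them by admitting fewer or more sequences. At a 4-fold threshold the 3 steps in order gave 395 and 957, 33 and 22, and 139 and 26, and the comparison of all fruiting stages with mycelium gave 262 and 754. With at least 20 FPKM in the higher library they gave 818 and 886, 93 and 53, 162 and 64, and 564 and 783. With no minimum they gave 1996 and 3774, 447 and 265, and 752 and 332, and 2617 sequences were lower in all fruiting stages. A pseudocount of 5 gave 106 and 60 in the second step and 237 and 73 in the third. Rescaling each library to a fixed equal sum gave 2149 higher in the first step, 335 and 197 in the second, 568 and 283 in the third, and 1386 higher in all fruiting stages. The same without the 50 most abundant sequences gave 2170 and 3626, 457 and 286, and 809 and 397, with 2773 lower in all fruiting stages. These last 2 scalings enlarge every value, so that more sequences pass 5 FPKM; with the mean total kept, the first step gave 1622 and 1697, and without the 50 most abundant 1371 and 1944. In all fruiting stages, the numbers were 1112 and 1397 with equal sums and the mean total kept, and 1200 and 1302 at the upper quartile, against 884 and 1657 as reported. The excess of lower over higher sequences in the first step was likewise open to scaling. The share of higher calls was 54.9% at the upper quartile, 48.9% with equal sums and 46.8% with median-of-ratios factors, against 39.5% as reported. Over all sequences, the median log2 difference shifted by 0.19, 0.11 and 0.09 (0.14 with the fixed equal sum and 0.10 with the length correction). Among sequences with sufficient FPKM, from which the calls come, the shifts were 0.26, 0.15 and 0.12 (0.16 and 0.07). The cause was not tested. In the later steps the higher calls outnumbered the lower under all alternatives (57.0% to 65.0% in the second step and 66.7% to 84.2% in the third). The 12 values of named sequences kept their direction in all 108 recalculations, with a smallest log2 difference of 2.54, under a pseudocount of 5. Under the alternatives other than pseudocounts the smallest was 4.25 and the largest shift 1.28. This is not a test of their direction, because these sequences were chosen for large differences and a pseudocount cannot turn a direction. Counting error left part of the calls near the threshold: the 95% counting interval of the fold lay wholly beyond 2 for 2819 of the 3316 calls in the first step, 222 of 301 in the second and 422 of 512 in the third. The alternatives on gene lists could not be run, since no identifier had a description. No paired analysis was possible because each stage had 1 library.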

Other observations

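The groups of profiles in this paragraph and the next were chosen after the values were seen; the tests of the 3 patterns that follow were set out before their results were known, except where a scaling is said to have been added later. Joined over the 3 steps, most called sequences differed only in the first: 1875 were lower and 1097 higher in primordium than in mycelium and were not called again. A small group of 20 sequences was higher in every step, with median FPKM of 1.91 in mycelium, 10.7 in primordium, 49.1 in young fruit body and 263 in mature fruit body. Its share of the fragments was 0.00788% in mycelium and 1.76% in mature fruit body. A further 227 sequences were called only in the last step, as higher in mature fruit body, with a median of 2.24 FPKM in young and 11.7 FPKM in mature fruit body. In the opposite direction, 4 sequences were lower in every step, with medians of 933, 336, 142 and 56.9 FPKM.

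Other groups were transient. Higher in primordium and then lower in both later steps were 18 sequences, with medians of 2.86, 53.3, 17.5 and 2.56 FPKM in order of stage, and 68 more were higher in primordium and lower only in the last step. Lower in young fruit body and then higher in mature fruit body were 15 sequences, where independent lists among the 6589 sequences that could be called in both steps would share 1.66 and simulated unchanged libraries at most 1. The excess was not particular to this group: 43 sequences were higher in both of these steps, against 4.86 for independent lists, 23 were lower in both, against 1.44, and 9 were higher and then lower, against 4.22. Of the 15, 10 had also been higher in primordium than in mycelium, with medians of 7.55, 106, 12.3 and 59.5 FPKM. These 10 came from 8 clusters or unigenes, and the values for independent lists count contigs of 1 cluster as separate sequences. Consecutive steps share a library, so a deviation of the young fruit body library alone would enter both steps. Among the 6000 sequences with at least 10 FPKM in some library, 2418 had their highest value in mycelium, 1055 in primordium, 1219 in young fruit body and 1308 in mature fruit body. The 3 fruiting libraries resemble one another and divide their highest values between them, so these numbers do not rank the stages. With at least 10 fragments in 1 library and 0 in the rest, which allows up to 3 in each of those, 36 sequences were found in mycelium, 1 in primordium, 0 in young fruit body and 13 in mature fruit body. For sequences with 1 value above 0, taking the smallest fitting length can understate the count, so these numbers may be too low.

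The first pattern was the 3316 calls between mycelium and primordium, 6.48 times those of the next largest step. Counting error alone gave at most 10 calls. A few abundant sequences did not account for it, since scaling without the 50 most abundant left 4.81 times the calls of the next largest step (3315 against 511 calls when the mean total was kept, a scaling added later that does not also enlarge the values), and removing the median change per length bin, against a length bias, left 6.36 times. A difference between these libraries other than stage (culture, extraction or sequencing) cannot be told apart from stage, because there was 1 library per stage. The biological difference between mycelium and fruiting tissue stays open on the same ground.

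The second pattern was 22 clusters, of 449 with at least 2 called contigs in that step, whose contigs were called in opposite directions. In the later steps this held for 1 of 38 and 0 of 70 clusters. When the fragments of each cluster were split independently between its contigs at the pooled share, all 20 simulated draws held 0 such clusters. This argues against counting error in such a split. Fragments shared between similar contigs, or assigned to 1 of them arbitrarily, were not simulated, so an effect of assignment stays open. Whether these clusters hold different genes or forms of 1 gene, such as splice forms or alleles, cannot be told apart for the 22 clusters without their sequences.

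The third pattern was the residue in primordium of the 15 sequences lower there than in mycelium by a log2 difference of at least 8. RNA with the profile of the mycelium library, carried into the primordium library, would leave them all at 1 ratio. The 95% counting intervals of only 33.3% of them (5 of 15) covered the pooled ratio of 0.130%. These intervals cover counting error only. The ratios ran from 0.0153% to 0.277%, which argues against carry-over of RNA with that profile as the whole residue. Carry-over of mycelial RNA with another profile was not tested. The lowest ratio, that of Unigene427 (5 fragments against 33839, interval 0.00495% to 0.0356%), leaves open a carry-over of RNA with the profile of the mycelium library up to that level.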
